A study of Mus musculus with 2 samples.

How the data were processed

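Small RNA from whole liver of mouse embryos at embryonic day 14.5 was sequenced as 2 libraries, which form the only group. The labels describe each as 1 liver but of mixed sex, so the number of embryos is uncertain. The samples are called the 2 livers below. Biological replicate numbers 1 and 2 were taken from the labels, which also give separate collection days but the same donor ID. Per the labels, the libraries hold RNA under 30 nucleotides and the genome assembly is mm10. Notes deposited with the files name annotation M4 and show that each table derives from its own alignment, so replicates were not pooled. The aligner, the counter, their versions and any trimming are not given in the sources used here.

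The deposited values are raw counts of reads per microRNA gene, not normalized. The deposited tables have no header. For each of 1973 genes they give a count regardless of strand, a count on the gene's strand and a count on the opposite strand, and the first is the sum of the others for every gene in both tables. Rows that name no gene were left out of library sizes and tests. These hold unmapped reads (18.6% and 17.7% of the 6395680 and 8068090 reads of replicates 1 and 2), reads mapped to more than 1 place (34.0% and 33.1%), reads in no gene on the same strand (10.6% and 10.4%) and ambiguous reads (0 in each). Because reads that map to more than 1 place are not in the gene counts, microRNAs made by several identical loci are counted too low. Opposite-strand counts (9.60% and 10.2% of gene counts) were not used in the main results.

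Gene symbols, positions and host genes were taken from the GENCODE M21 annotation of GRCm38, the same assembly as mm10, by Ensembl gene ID without version. Of the 1973 IDs, 1894 matched. The 79 others held 3 counts in total. A host gene is a gene of another type that spans the microRNA on the same strand. Of the 332 genes with at least 10 counts in each library, 76 share a stretch of 20 bases with another annotated hairpin and are called uncertain where they are named for their level.

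Same-strand counts were scaled to CPM by the library totals of 2353946 and 3132763. At this depth a count of 0 allows up to 3 counts, which is 1.27 CPM in replicate 1 and 0.958 CPM in replicate 2. Shares in 1 library have 95% Clopper-Pearson intervals, and ratios between the libraries have 95% exact binomial intervals. All of these cover counting error only. Genes with at least 10 counts in each library were compared between the 2 libraries by a two-sided exact binomial test given the library totals, with Benjamini-Hochberg adjustment and a threshold of 0.05. The correlation uses log2(CPM + 1). Log ratios are log2 ratios of counts per library total with 0.5 added to each count, so they understate the difference of low genes, whereas fold ratios carry no pseudocount. The coefficient of variation is the square root of edgeR's common dispersion with an intercept alone and TMM scaling. Since there is 1 library per liver, no p-value was computed for lists. A list's median log2 ratio was placed among 10000 random lists of the same size, each member replaced by 1 of the 40 genes nearest in mean CPM. A list's median level was placed among random lists from all 1973 genes.

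Before the data were examined, 16 lists were fixed: hepatocyte, erythroid, white cell, endothelial and megakaryocyte, mesenchymal, epithelial and biliary, muscle, neural, pancreas and gut, let-7, miR-17-92, Dlk1-Dio3, H19-Igf2 and Mest, Sfmbt2, hypoxia and p53, and genes with the same mature sequence. List members with no row under the listed symbols were not analysed here. The rule for named genes, fixed at the same time, took the 20 highest genes, the 3 highest members of each list, the 5 largest log2 ratios in each direction among genes with a mean of at least 100 counts, and Mir122, Mir451a, Mir144, Mir142, Mir223, Mir126 and Mir483 whatever their level. Mir142 was not analysed here under its own ID, and Mir126 stands under its symbol Mir126a. Other members are named where a list is described.

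The alternatives planned were a minimum of 1 or 100 counts or none, counts regardless of strand, pseudocounts of 0.1 and 10, TMM and DESeq2 scaling, DESeq2's gene-wise dispersion, leaving the highest gene out of the totals and leaving out each replicate. Those added later were the coefficient of variation without genes differing by over 2-fold, list percentiles among detected genes, opposite-strand counts for absent list members, a list of Hox cluster microRNAs and the number of differing genes per list by TMM and DESeq2 scaling. The steps were tested on simulated data drawn from the real means and library sizes, with known folds given to a set of genes. Of 340 simulated genes tested by the exact binomial test, 4 of 144 unchanged genes were called (2.78%). So were 60.8% of genes changed by 1.25-fold, 84.3% of genes changed by 1.5-fold, 84.8% by 2-fold and 100% by 4-fold. That test was given the real library totals, which are the true scaling of the simulated counts, and not the simulated totals. These rates therefore do not cover false calls that come from scaling. A simulated coefficient of variation of 20% over 332 genes was estimated as 18.5%. The software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0. The notes deposited beside each table hold no measurements and were used only for the assembly and annotation.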

Results

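MicroRNA sequencing was carried out on whole livers of mouse embryos of strain B6NCrl at embryonic day 14.5. At this stage the fetal liver holds immature liver cells and is also the main site of red blood cell formation. Total RNA was made into libraries of RNAs under 30 nucleotides, and reads were counted at annotated microRNA genes. There was 1 group with 2 libraries, replicate 1 and replicate 2, labelled as biological replicates collected on different days and called the 2 livers here. The labels describe each sample as a single liver yet give its sex as male and female pooled and the same donor ID for both, so how far the samples are independent animals is uncertain. The libraries held 6395680 and 8068090 reads, of which 2353946 and 3132763 were counted at microRNA genes on the gene's own strand. Levels are given as CPM, the usual depth-scaled count relative to these same-strand totals, or as a percent of the totals, and a value after ± is the SD over the 2 livers (n = 2). Coordinates are those of the mouse genome build GRCm38 (mm10). With a single group, the design allowed a description of the microRNAs of this tissue and a comparison of the 2 livers. No comparison between conditions was possible.

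The first question was which microRNAs the liver of this stage held. Mir122, the microRNA most typical of liver cells, was the most abundant gene with 103860 ± 9208 CPM. It took 9.73% of the counts in replicate 1 (95% Clopper-Pearson interval 9.70 to 9.77) and 11.0% in replicate 2 (11.0 to 11.1). Mir122 lies on chromosome 18 from 65248861 to 65248926, within an exon of the transcript AC157910.3. The second was Mir126a with 59586 ± 2731 CPM, a microRNA of the cells lining blood vessels, which lies on chromosome 2 from 26591357 to 26591429 within the Egfl7 gene. They were followed by Mir411 (39382 ± 1312 CPM), Mir26b (38616 ± 494.1 CPM, in an intron of Ctdsp1), Mirlet7g (35948 ± 832.1 CPM, in an intron of Wdr82) and the red cell microRNA Mir451a (34131 ± 5499 CPM). Next were Mir17 (32370 ± 1264 CPM), Mir335 (31747 ± 1380 CPM), Mir21a (27880 ± 3248 CPM) and Mirlet7i (23409 ± 122.1 CPM). These 10 genes together took 42.7% ± 0.0374 of the counts. Ranks 11 to 20 went from Mir431 with 22564 ± 637.1 CPM to Mir154 with 15808 ± 1577 CPM, and between them were Mir30e, Mir127, Mir22, Mir322, Mir20a, Mir130a, Mir143 and Mir99a. In both libraries 332 of the 1973 genes in the table had at least 10 counts. That number was 542 with at least 1 count and 215 with at least 100 counts. Intervals cover counting error only, since reads made by PCR are not independent molecules. These ranks and shares leave out reads that map to more than 1 place (34.0% and 33.1% of reads). Genes with several copies may therefore rank too low. Mir142, not analysed here under its own ID, is missing from the ranking, and the opposite-strand counts at its locus would take rank 3.

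The lists for liver cells, red blood cells, vessels and connective tissue each held several percent of the counts, mostly from their highest members. The hepatocyte list held 11.3% ± 0.960 of the counts with 6 of its 7 measured members at 10 or more counts in each library. Mir122 made up most of it, followed by Mir192 (4555 ± 123.9 CPM, chromosome 19 from 6264844 to 6264932) and its neighbour Mir194-2 (2206 ± 152.3 CPM). The endothelial and megakaryocyte list held 7.68% ± 0.967 with 7 of 7 members detected and Mir126a highest in both libraries. Mir99b had 6234 ± 0.305 CPM, while Mir10a had 7584 CPM in replicate 1 and 3549 CPM in replicate 2, and Mir10b 6365 and 582.9 CPM. The erythroid list held 4.64% ± 0.717 with 7 of 7 members detected. Its first members, Mir451a and Mir144 (10433 ± 1642 CPM), lie next to each other on chromosome 11 between 78073005 and 78073241, and Mir210, which is also a microRNA of the hypoxia response, reached 900.9 ± 52.5 CPM. The mesenchymal list held 4.56% ± 0.387 with 7 of 13 members detected. Mir21a, which lies in an exon of Vmp1, and Mir143 (16236 ± 845.9 CPM) made up nearly all of it, so its level says little about the other members. Mir214 (1024 ± 214.0 CPM, in an exon of Dnm3os) came next.

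The white cell list was lower, with 12464 ± 470.4 CPM by strand-specific counts and 9 of 11 members detected. Mir223, a microRNA of granulocytes and monocytes (10191 ± 433.1 CPM, chromosome X from 96242817 to 96242926), made up most of it, ahead of Mir342 (1391 ± 18.4 CPM, in an intron of Evl) and Mir181a-1 (369.6 ± 42.0 CPM). Mir142, which most blood cells express, was not analysed here under its own ID. Mir142b, annotated on the other strand of the same locus, had 1 same-strand count in each library but 126731 and 180061 opposite-strand counts. An alternative chosen after the data were seen included such counts for list members annotated only on the other strand. By it the white cell list came to 68121 CPM, above the erythroid (46443 CPM) and mesenchymal (45601 CPM) lists. The epithelial and biliary list held 1.77% ± 0.115 with 10 of 10 members detected, led by Mir30a (13628 ± 899.0 CPM), Mir429 (1671 ± 107.1 CPM) and Mir31 (814.5 ± 98.1 CPM).

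The list with the highest level came from an imprinted region. The Dlk1-Dio3 list, a region of chromosome 12 where the copy inherited from the mother gives a long series of microRNAs, held 19.9% ± 0.735 of the counts, and 42 of its 46 measured members were detected. Its first members were Mir411 (109710175 to 109710256), Mir431 (109590447 to 109590537) and Mir127 (20218 ± 1105 CPM, 109592846 to 109592915). Mir411 shares a stretch of 20 bases with another hairpin, so its level is uncertain. The list of the H19, Igf2 and Mest loci held 3.52% ± 0.0459, nearly all from Mir335 in an intron of Mest (chromosome 6 from 30741299 to 30741396). Mir483, in an intron of the growth factor gene Igf2, had 3270 ± 911.5 CPM, and Mir675, in an exon of H19, had 151.4 ± 9.29 CPM. In the Sfmbt2 list of near-identical copies, 8 of 34 measured members were detected and the list held 0.331% ± 0.0168. Mir467d (1044 ± 44.2 CPM), Mir467c (887.7 ± 24.9 CPM) and Mir467e (771.8 ± 58.7 CPM) led it, each uncertain because of shared sequence.

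The miR-17-92 list of growth-associated polycistrons held 9.11% ± 0.275 with 15 of 15 members detected. Mir17 and Mir20a (17940 ± 890.1 CPM) lie in the host transcript Mir17hg on chromosome 14, and Mir93 (13561 ± 177.8 CPM) lies within the Mcm7 gene on chromosome 5. The let-7 list held 6.90% ± 0.0930 with 10 of 10 measured members detected, led by Mirlet7g, Mirlet7i and Mirlet7d (4552 ± 65.5 CPM). Mirlet7a-1, Mirlet7a-2, Mirlet7c-1, Mirlet7c-2 and Mirlet7f-2 share their mature product with another locus and are counted too low. Mirlet7e and Mirlet7f-1 were not analysed here under their own IDs. The sum of this list is therefore a lower limit, and the order of its members is uncertain. The hypoxia and p53 list held 0.107% ± 0.00362 with 4 of 4 members detected. After Mir210 it held Mir34c (99.1 ± 11.0 CPM) and Mir34a (60.9 ± 3.76 CPM), which the p53 protein induces. Genes whose mature product is also made by another locus held 2.77% ± 0.0263 with 40 of 57 members detected, led by Mir16-1 (7236 ± 143.9 CPM), Mir101b (6966 ± 208.6 CPM) and Mir92-1 (5724 ± 650.1 CPM). Their levels are lower limits, since 34.01% and 33.07% of all reads mapped to more than 1 place and were not counted at any gene. Mir194-2, Mir181a-1, Mir7-1, Mir128-1 and Mir219a-2 also share a 20-base stretch with another hairpin and are uncertain in the same way.

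MicroRNAs of neighbouring tissues were low among reads that map to 1 place. Many neural members, and the Mir1a and Mir133a copies of the muscle list, share their mature product with another locus. Reads mapping to more than 1 place were not counted, so the sums of these lists are lower limits. The pancreas and gut list held 0.167% ± 0.00663 with 8 of 11 members detected, led by Mir375 (948.2 ± 35.4 CPM), Mir196b (422.7 ± 39.0 CPM) and Mir7-1 (224.1 ± 20.8 CPM). The neural list held 0.0527% ± 0.0275 with 9 of 16 members detected. It differed by library, with 0.0722% in replicate 1 and 0.0333% in replicate 2, and so did the order of its members. Mir137 had 242.1 CPM in replicate 1 and 22.3 CPM in replicate 2, Mir128-1 149.96 and 131.8 CPM, and Mir132 100.3 and 78.5 CPM. The muscle list held 0.0299% ± 0.00228 with 3 of 9 members detected, which were Mir499 (265.5 ± 10.2 CPM, in an intron of Myh7b), Mir206 (31.0 CPM in replicate 1 and 14.05 CPM in replicate 2) and Mir208b (5.47 ± 1.87 CPM). Members with no count, such as Mir124a-2 and Mir1a-1, allow up to 3 counts, or 1.27 CPM in replicate 1 and 0.958 CPM in replicate 2, for reads that map to 1 place. Against 10000 random lists of the same size from all annotated microRNA genes, the median level of the Sfmbt2 list lay at percentile 47.2 and that of the muscle list at 96.0. The other 14 lists lay at percentile 98.9 or above. Most annotated genes had few or no counts, and among detected genes alone, an alternative chosen after the data were seen, the percentiles were much lower for several lists. There the same mature sequence list lay at 5.37, pancreas and gut at 3.21, neural at 9.44, muscle at 14.2, hypoxia and p53 at 30.8, white cell at 46.2, miR-17-92 at 53.3, mesenchymal at 60.5, Sfmbt2 at 63.2, epithelial and biliary at 75.2 and erythroid at 76.3. The let-7 list lay at 91.5, H19-Igf2 and Mest at 92.1, hepatocyte at 96.1, endothelial and megakaryocyte at 98.7 and Dlk1-Dio3 at 99.99.

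**Figure D1:**
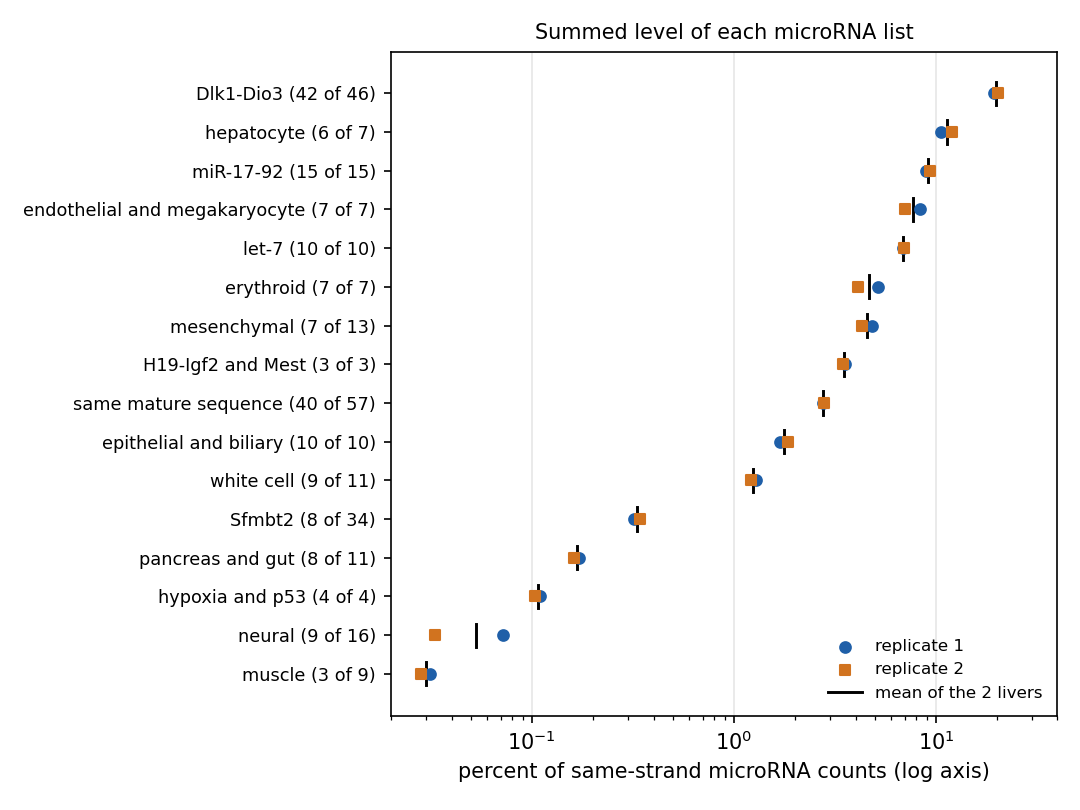
Summed level of each microRNA list as percent of same-strand counts, on a log axis. Circles are replicate 1, squares are replicate 2 and vertical bars their mean, with the number of members at 10 or more counts in each library out of those measured in brackets. The Dlk1-Dio3 list is highest with 19.9% and the muscle list lowest with 0.0299%, and the neural list has the widest gap between the livers. The white cell value does not include Mir142.

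The second question was how far the 2 livers differed. Most microRNAs had nearly the same level in both, while a small set was several times higher in replicate 1. Mir10b, which lies in introns of Hoxd3 and Hoxd4 on chromosome 2 from 74726070 to 74726137, was 10.9-fold higher in replicate 1 (95% exact interval 10.4 to 11.5), with 6365 against 582.9 CPM. Mir137, a microRNA of neurons on chromosome 3 (118433857 to 118433929), was 10.8-fold higher (8.44 to 14.1) with 242.1 against 22.3 CPM. Mir135b was 10.1-fold higher (7.24 to 14.5), Mir92b was 6.97-fold higher (4.81 to 10.4), and Mir615, in an intron of Hoxc5 on chromosome 15 (103014910 to 103015001), was 6.68-fold higher (5.57 to 8.06). In the other direction the ratios were smaller. Mir6236 was 1.93-fold higher in replicate 2 (1.55 to 2.42), Mir1247, in an exon of Dio3os, 1.87-fold (1.42 to 2.49), Mir505 1.495-fold (1.17 to 1.92), Mir483 1.49-fold (1.45 to 1.54) and Mir293 1.45-fold (1.10 to 1.91).

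Across the 332 genes, log2(CPM + 1) had a Pearson's r of 0.987 and a Spearman's rho of 0.982 between the livers. Genes are not independent replicates, so no p is given. By a two-sided exact binomial test of each gene's counts with Benjamini-Hochberg adjustment, 136 genes (41.0%) differed at an adjusted p under 0.05, of which 59 were higher in replicate 1 and 77 in replicate 2. This balance depended on the scaling, with 69 against 59 by TMM and 69 against 58 by DESeq2 size factors, so no excess toward either liver is claimed. No gene called both by library totals and by another scaling changed direction. At an unadjusted p under 0.05 there were 159. This test compares these 2 libraries, not conditions, and it shows that they were not the same library deposited again. The median absolute log2 ratio was 0.16. Of the genes that differed, 15 were over 2-fold higher in replicate 1 and 1, Mir291a, was over 2-fold higher in replicate 2. Mir291a is named after its value was seen. The coefficient of variation between the livers beyond counting error was 24.95% by edgeR's common dispersion. It was 9.87% without the 18 genes over 2-fold in log2 ratio, whether or not they passed the test, an alternative chosen after the data were seen. Leaving out the most different genes lowers it by construction. The median by DESeq2's gene-wise dispersion was 2.53%, which is a median over genes and not a common value.

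**Figure D2:**
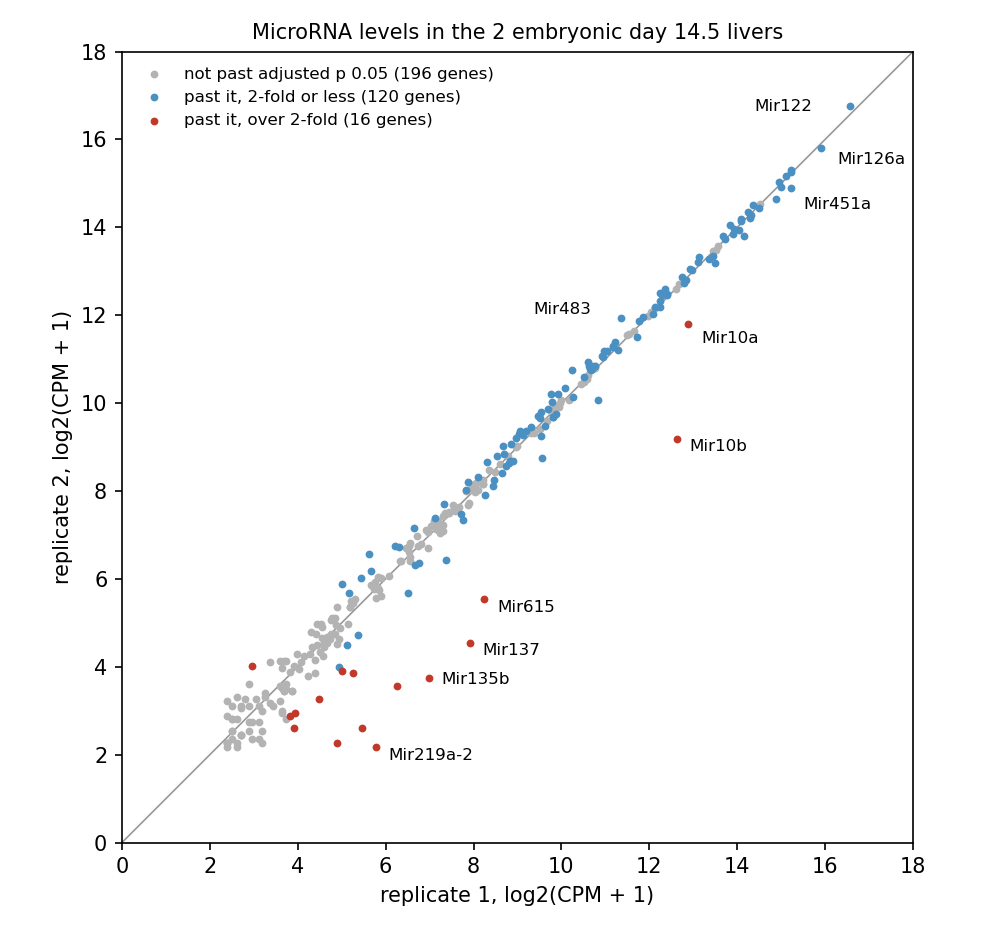
Level of each of the 332 microRNA genes with at least 10 counts in each library, as log2(CPM + 1) in replicate 1 (horizontal) and replicate 2 (vertical), with the line of equal levels. Red points are the 16 genes past an adjusted p of 0.05 with over 2-fold difference, blue points the other 120 past it and grey points the 196 not past it. All but 1 of the red points lie below the line, toward replicate 1.

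By list, the clearest difference was in the neural list, which was 2.17-fold higher in replicate 1 (95% exact interval 2.01 to 2.34). All 9 detected members were higher there, and 7 differed by the exact test, both over all genes tested and adjusted over the list alone. The median log2 ratio of replicate 2 over replicate 1 was -0.67, at percentile 0.245 among 10000 random lists matched on expression. Mir137 and Mir219a-2 (54.0 against 3.51 CPM) had the largest ratios, while Mir128-1 was 1.14-fold higher with an interval of 0.984 to 1.31. The pancreas and gut list had a median of -0.32 (percentile 1.71), with 3 of its 8 detected members higher in replicate 1 by the test and 4 adjusted over the list alone. With at least 100 counts in each library its median was -0.19, at percentile 5.17. The 3 members were Mir7b, Mir196a-2 and Mir196b, and the last 2 also lie in the Hox gene clusters described below. The muscle list had a median of -0.70 over only 3 members (percentile 2.41, with many random lists tied at its value), of which Mir206 passed the test. Drawn up after the data were seen, a list of 5 detected microRNAs inside the Hox gene clusters was 3.22-fold higher in replicate 1 (3.16 to 3.28). All 5 passed the test. Because the list came from genes already seen to differ, its values describe them and are no test of the list. They were Mir10a, Mir10b, Mir615, Mir196a-2 and Mir196b. Mir10a and Mir10b also belong to the endothelial and megakaryocyte list, and Mir196a-2 and Mir196b to the pancreas and gut list, so these lists do not differ independently.

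The Dlk1-Dio3 list differed the other way by a small amount. Its median log2 ratio was 0.13, at percentile 99.8, and 36 of its 42 detected members were higher in replicate 2. By the exact test 29 members differed, 26 of them higher in replicate 2 and 3 higher in replicate 1, and 30 differed adjusted over the list alone. By TMM or by DESeq2 size factors 24 differed, 20 of them higher in replicate 2. The members lie in the same imprinted region, whereas the random lists replaced each member separately. Over all adjacent pairs of detected genes the log2 ratios differed by a mean of 0.21, against 0.35 over random re-pairings. The random range may therefore be too narrow for this list, and the members that differed are not independent of each other. The list of genes with a shared mature product had a median of -0.10 (percentile 0.55), or -0.05 (percentile 1.06) with at least 100 counts in each library, with 10 of 40 members higher in replicate 1 and 4 higher in replicate 2, 14 in all and likewise 14 adjusted over the list alone.

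In the other 11 lists the median lay inside the central 95% of matched random lists, although single members differed. In the hepatocyte list (median 0.15, percentile 95.3) 4 of 6 detected members, Mir122, Mir192, Mir194-2 and Mir455, were higher in replicate 2 and none in replicate 1. Mir192 did not pass by TMM or DESeq2 size factors. In the erythroid list (-0.12, percentile 3.69) 4 of 7 were higher in replicate 1, among them Mir451a (38020 against 30243 CPM) and Mir144 (11594 against 9272 CPM), and Mir486 was higher in replicate 2. In the endothelial and megakaryocyte list (-0.06, percentile 9.15) 3 of 7 were higher in replicate 1, which were Mir126a, Mir10a and Mir10b. In the white cell list (-0.03, percentile 22.6) 2 of 9 were higher in replicate 1 and 1 in replicate 2. In the mesenchymal list (-0.01, percentile 30.5) Mir21a and Mir143 were higher in replicate 1 and Mir214 in replicate 2. In the epithelial and biliary list (0.15, percentile 91.6) 4 of 10 were higher in replicate 2 and 1 in replicate 1. In the miR-17-92 list (0.07, percentile 75.4) 7 of 15 were higher in replicate 2, Mir17 and Mir20a among them, and 1 in replicate 1, against 4 and 2 by TMM or DESeq2 size factors. In the let-7 list (-0.0034, percentile 19.1) 2 of 10 were higher in replicate 1, and Mirlet7g in replicate 2, while 3 were higher in replicate 1 by TMM or DESeq2 size factors and Mirlet7g did not pass by the latter. In the list of the H19, Igf2 and Mest loci (0.12, percentile 81.4) Mir335 was higher in replicate 1 and Mir483 in replicate 2. The Sfmbt2 list (0.10, percentile 76.0) and the hypoxia and p53 list (0.18, percentile 80.0) each had 1 member that differed, Mir467e and Mir210. For each of these 11 lists, the count adjusted over the list alone was the same as that over all genes tested. Per the labels each library comes from its own liver, and with 1 library each these values describe the 2 libraries.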

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

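The tests of the 2 patterns weighed here were chosen after the results were seen, apart from the exact test of single genes. The design has 1 group, so no biological explanation was tested for either.

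Counts on the strand opposite to the annotated gene, which the comparisons above do not use, were above the 3 counts that a count of 0 allows in both libraries at 19 loci. The mean over the 2 libraries was 153396 counts at Mir142b, 48345 at Gm24321, 35315 at Gm25252, 20370 at Gm25301, 17864 at Gm24083, 13865 at Mir299b, 8542 at Gm25750 and 4650 at Gm25927. At these 8 loci it was at least 1000 and above the same-strand counts. It was 794.5 at Mir497b, 192.5 at Gm24111, 179.5 at Mir486, 105.5 at Mir337, 69 at Mir3074-1, 50.5 at Mir130a, 36.5 at Mir126a, 18 at Mir203, 17.5 at Mir129-2, 7 at Mir3071 and 4 at Mir7654. At Mir142b (chromosome 11 from 87756841 to 87756955) they would take rank 3 among all genes. The first 8 loci held 99.5% of all opposite-strand counts in each library.

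A loss of strand information in the libraries is argued against, because the highest opposite-strand share was 0.859% among the 127 genes with at least 1000 same-strand counts in each library, and 111 of these had no opposite-strand count at all. A candidate explanation is a microRNA on the other strand that was not counted here under its own ID. Of the 1894 matched genes, 32 have such a microRNA in M21, and at least 99.9% of the opposite-strand counts of either library lay at them. At the first 8 loci these are Mir142, Mir409, Mir376a, Mir378a, Mir191, Mir299a, Mir380 and Mirlet7e.

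Mir10b, Mir137, Mir135b, Mir92b and Mir615 were among 15 microRNAs over 2-fold higher in replicate 1, of which 4 are on the neural list and 4 lie in the Hox clusters. Counting error is argued against, for the neural part, since the interval of the ratio of the neural list had a lower bound of 2.01. The interval given above for the Hox cluster list is no such test, since that list was drawn up from these genes. The exact test of single genes, adjusted over all 332 genes, does not depend on that list. All 5 detected Hox cluster members passed it, so counting error is argued against for them too. Reads shared between near-identical copies are argued against for members that share no 20-base stretch with another hairpin. In the neural list these are Mir137, Mir132 and Mir212, together 3.32-fold higher in replicate 1 with a lower bound of 2.92. This sum rests mostly on Mir137, and it is 1.35-fold (1.13 to 1.60) without Mir137 and 8.83-fold without Mir132. Shared reads stay open for the other 6 of the 9 detected neural members and for 1 of the 5 in the Hox clusters. The list of genes with a shared mature product cannot decide this. Its median log2 ratio lay at percentile 0.55, toward replicate 1, and 28 of its detected members were higher there against 12 in replicate 2. Without neural and Hox cluster members the median lay at percentile 3.755, just above the limit of 2.5. The summed level of the whole list was slightly higher in replicate 2 (ratio 0.987, 0.977 to 0.997). That sum leans on high members such as Mir92-1, which had 5264 CPM in replicate 1 and 6184 CPM in replicate 2. RNA of neural tissue in the replicate 1 library, from dissection or from another library, stays open for the neural part. The percentile of 0.245 is the value that showed the pattern and so lends it no support, and it cannot be told apart from a difference of the liver itself. Of the list's 16 measured genes 13 also stand on the list of genes with the same mature sequence, and none on another tissue list. Mir137 (242.1 against 22.3 CPM) had the highest level in replicate 1. The copies of Mir124a, abundant in neurons, had at most 1 count where reads mapping to several places are not counted. Mir9-3, also on the neural list, had 38 counts in replicate 1 and 2 in replicate 2, and its copy Mir9-2 had none.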

How the results depend on the processing

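The alternatives added after seeing the data are the coefficient of variation without genes differing by over 2-fold, list percentiles among detected genes, opposite-strand counts for absent members, the Hox cluster list and differing genes per list by other scaling. For the numbers of genes, the top 10 share, the correlation, the coefficient of variation, the list levels and the list shifts, 51 values stayed and 36 moved, judged by their spread, by 1.5 times for counts or by whether a list's shift lay outside matched random lists. Leaving out a replicate and other scaling of the list shifts are not counted, since their outcome was fixed. For single genes, differing genes per list and the Hox cluster list 175 stayed and 2 moved, both of Mir99b by under 1 CPM. Most of these are mean CPM values of single genes by TMM or DESeq2 scaling. Such scaling moves the libraries slightly in opposite directions (TMM factors 0.989 and 1.011), so a mean stays within its SD unless both libraries are almost equal. These values, and the list levels by TMM among the 51, therefore test little. The number of differing genes stayed within 1.5 times, but its balance turned from 59 higher in replicate 1 and 77 in replicate 2 to 69 and 59 by TMM and 69 and 58 by DESeq2, with 118 and 117 genes shared with library totals. With 2 livers the SD always exceeds the change from leaving out either. Without replicate 1 the neural list fell from 527.4 to 332.9 CPM and Mir10a from 5566 to 3549, over 1.5 times each. No paired analysis was possible because there is only 1 group. In the muscle and neural lists each member had under 1000 counts in each library.

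Fewer or more genes passed with another minimum by construction, 542 with at least 1 count and 215 with at least 100. The top 10 share was 41.4% regardless of strand, r was 0.991 with a pseudocount of 10, and the coefficient of variation was 2.53% by DESeq2 and 9.87% without genes differing by over 2-fold. The pancreas and gut shift was -0.19 with at least 100 counts. The coefficient of variation falls by construction when the genes over 2-fold are left out. The cause was not tested for the top 10 share, r, the DESeq2 value and the pancreas and gut shift.

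Leaving Mir122 out of the totals raised every list by construction, and these past their SD, to 126475 CPM (hepatocyte), 13906 (white cell), 50867 (mesenchymal), 19795 (epithelial and biliary), 333.1 (muscle), 1865 (pancreas and gut), 77014 (let-7), 101657 (miR-17-92), 221853 (Dlk1-Dio3), 39244 (H19-Igf2 and Mest), 3694 (Sfmbt2), 1190 (hypoxia and p53) and 30927 (same mature sequence). Counts regardless of strand enlarge the totals and gave 102019 CPM (hepatocyte), 61355 (white cell, which gains the Mir142b locus), 41084 (mesenchymal), 15976 (epithelial and biliary), 269.1 (muscle), 1506 (pancreas and gut), 62156 (let-7), 82034 (miR-17-92), 183563 (Dlk1-Dio3), 31680 (H19-Igf2 and Mest), 2980 (Sfmbt2), 960.5 (hypoxia and p53) and 25026 (same mature sequence). Opposite-strand counts for absent members gave 68121 CPM (white cell), 70759 (let-7) and 237208 (Dlk1-Dio3).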

Other observations

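The test of neighbouring pairs below was written down before its result was seen, and the groups of genes and the 10 kb limit were chosen after the levels of single genes had been seen.

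Grouping detected genes on the same strand within 10 kb of each other gave 43 groups with 152 genes. Besides the Dlk1-Dio3 groups, Mir17 and its 5 neighbours on chromosome 14 (115043671 to 115044506) summed to 64403 ± 3044 CPM (SD, n = 2), Mir144 and Mir451a to 44564 ± 7141 CPM, and Mir25, Mir93 and Mir106b on chromosome 5 (138165321 to 138165818) to 26034 ± 343.3 CPM. The Mir322 to Mir450b group on chromosome X from 53047997 to 53054349 (7 genes) summed to 23572 ± 1018 CPM, most of it from Mir322. Mir15a and Mir16-1 summed to 22372 ± 553.3 CPM, and the 6 genes of the miR-30 family, spread over the genome, to 40018 ± 2660 CPM. The Mir290a to Mir295 group, typical of embryonic stem cells, was low, with 114.4 ± 22.4 CPM and 4 of 6 genes at 10 or more counts in each library.

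Within a group, counted levels differed widely. The highest member stood a median of 14.9-fold above the lowest, with 3.27-fold for Mir144 and Mir451a and 861-fold for the Mir17 group. There the lowest, Mir19b-1, shares its mature product with Mir19b-2 and is counted too low. Other lowest members share a 20-base stretch with another hairpin, such as Mirlet7c-1 below Mir99a (554-fold) and Mir30c-1 below Mir30e (193-fold). Their levels are uncertain. Mir301b below Mir130b (80.1-fold) and Mir145a below Mir143 (64.8-fold) share no such stretch. The median mixes both kinds of group and is no measure of spread among fully counted members.

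Across the livers, by contrast, neighbours differed by similar amounts. The mean absolute difference of the log2 ratios was 0.21 over 109 adjacent pairs and 0.35 over random re-pairings matched on expression, and 100% of 10000 re-pairings had a larger mean. Without Dlk1-Dio3 members it was 0.23 against 0.39 over 68 pairs, and without genes differing by over 2-fold 0.20 against 0.26 over 107 pairs (99.96% larger). A shared primary transcript is a candidate explanation, as a hypothesis from 2 libraries. Similar cells of origin or similar sequence of neighbours were not tested.

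The difference of the endothelial and megakaryocyte list between the livers rested mostly on Mir10a and Mir10b. With both it was 8.36% against 7.00% of counts, and without them 6.97% against 6.58%, a ratio of 1.06 (95% exact interval 1.05 to 1.07).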
